A study of Caenorhabditis elegans with 8 samples.

How the data were processed

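RNA was taken from whole worms brought to young adulthood together by a timed egg lay, and libraries were made from polyadenylated RNA, per the labels' protocols. The 8 libraries fall into 2 strains, N2 and HC125, in 2 experiments with 2 libraries of each strain. The experiments differ in library kit, read layout and strandedness, per the labels. They were therefore kept apart throughout, and values were never compared across tables except as ratios within each. The submitters' processing notes name TopHat2 2.0.1 and Cufflinks 2.2.1, without their order or settings. The genome build and annotation are not given in the sources used here. Of the 20541 gene identifiers in the tables, 20194 are in the WBcel235 annotation, all on the same chromosome. Among the 2583 genes whose start and end differ from that annotation by the same amount, 97.4% have no shift, so positions are given as the files list them, counted from 1.

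Each experiment has 1 table in the layout of Cuffdiff, per the file headers, with the test of HC125 against N2. The FPKM values were computed by the authors, with 1 value per strain that combines its libraries. They are normalized for gene length and library size. The test statistic is a score the authors' tool gives per gene, and the p-value and the q-value, which is adjusted for the number of genes tested, were also deposited by the authors. Recomputing the q-values from the p-values by the Benjamini-Hochberg method over genes with a completed test gave the same values up to rounding. The tables give no depth, and with several libraries and fractional read assignment behind each value no whole-read steps were recovered, so no counting intervals are given. FPKM estimated without strand can mix a gene with its antisense neighbour in the paired-end experiment, and reads shared by near-identical genes can be split in either. The tables' own fold column holds spreadsheet error text in place of infinite values and was not used. Genes marked as failed (2 in the paired-end and 13 in the single-end table) or as too deep (5 and 3) were left out, since they have no completed test. Yolk genes are among the latter. Genes marked as too low to test numbered 5420 and 7375.

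A gene was called at a deposited q of 0.05 or less. The words rose and fell are kept for genes called in both tables in the same direction. The overlap of calls was tested with Fisher's exact test, one-sided, per direction, over genes tested in both. Ratios are HC125 over N2, either of FPKM or, for lists and correlations, on the log2(FPKM + 1) scale, which understates the change of low genes. The standard error of a log2 ratio was taken as the ratio divided by the authors' test statistic. The 95% intervals and the z tests between genes or experiments rest on it and on a normal approximation. These errors need not match the deposited p-values, and among the named genes they were more often wider than those imply. For ugt-63 in the single-end experiment the 95% interval of the ratio was 0.473 to 1.04, though the authors' deposited p was 0.0140. The reverse occurs too: for col-175 there, the interval was 1.43 to 86.0 with a deposited p of 0.083. No fold is given where a strain is listed at 0.

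The 20 gene lists, the thresholds, the tests and the rule for named genes were set before the data were examined. The rule takes sid-1 and the other systemic RNA interference genes; up to 12 genes per direction called in both tables at 1 FPKM or more; per list up to 4 members called in both, or else up to 2 members of highest mean value; and up to 4 genes called in both in opposite directions, of which there were none. Genes outside the rule are said to be chosen after their values were seen. This also holds for ugt-63, F14F9.5, the other genes of the chromosome V repeat, all genes named for a call in 1 table and those in the closing section. Of the listed members, 834 genes were found and 4 names were not. A list's median ratio was set against 10000 random lists of the same size drawn from genes tested in both tables and matched on mean FPKM in 20 bins; this describes these libraries and is no test across replicates. Yolk genes were too few for it.

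Alternatives were a stricter q, a filter on low FPKM, a minimum ratio, other pseudocounts, centring on the median ratio, a Stouffer combination of both tables' p-values, and limma on the 2 ratios per gene; 2 more were added after seeing the data. The calling, combining and list steps were tested on simulated data with the genes and implied errors of both tables and 200 changed genes. At true log2 changes of 1, 2, 3 and 4, calls in both tables recovered 2%, 38%, 70% and 72% of 50 genes each, over 12954 genes, and the Stouffer combination 42%, 78%, 90% and 94%. limma on the 2 ratios recovered none at any size. The simulated p-values were computed from the implied errors, which are often wider than the deposited p-values imply. Through these errors the recovery rates may understate what calls on the deposited values could find. The 200 changed genes can work the other way. They outnumber the 32 and 16 genes called in the paired-end and single-end experiments, and more discoveries loosen the adjusted threshold. The rates are therefore no lower bound. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for figures.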

Results

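Polyadenylated RNA was sequenced from whole young adult Caenorhabditis elegans of 2 strains, the wild type N2 and HC125. The series design names wild-type worms and worms with a Psid-1::gfp transgene, in which the promoter of the gene sid-1 drives green fluorescent protein. Since N2 is the wild type, HC125 is read here as the transgenic strain. There were 4 libraries of each strain, split evenly over 2 experiments. The paired-end experiment used an unstranded kit (replicates 1 and 2 of each strain), and the single-end experiment used a stranded kit (replicates 3 and 4). The deposited tables give 1 pooled FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene, strain and experiment, so no spread between libraries is printed here. Each table lists 20541 genes. At 1 FPKM or more it held 12650 genes in N2 and 12771 in HC125 in the paired-end experiment, and 11282 and 11296 in the single-end experiment. The number of reads behind the values is unknown. The error given with a log2 ratio is the standard error implied by the authors' test statistic. Its median over genes was 0.59 in the paired-end and 0.36 in the single-end experiment, on the log2 scale. No label says whether replicates came from separate cultures, so the authors' p-values measure the spread between these libraries, which may be technical.

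The title of the series speaks of heritable silencing at an endogenous locus, and the transgene carries the sid-1 promoter, so sid-1 was examined before the other genes. The RNA of sid-1, which encodes a membrane channel for double-stranded RNA needed for systemic RNA interference, fell in HC125 in both experiments. It went from 31.9 to 2.11 FPKM in the paired-end experiment and from 12.9 to 0.818 FPKM in the single-end experiment. HC125 thus held 6.61% of the N2 level (95% interval 2.99 to 14.6%) in the first and 6.36% (3.36 to 12%) in the second. The log2 ratio of HC125 over N2 was -3.92 ± 0.58 (implied SE) and -3.98 ± 0.47. On the log2(FPKM + 1) scale it was -3.40 and -2.93, since the pseudocount of 1 shrinks the ratio of a gene at low level. In the authors' deposited tables sid-1 had p = 5e-05 in both, the smallest p either table lists, with q = 0.0270 and q = 0.0411. That p was shared by 28 genes in the paired-end and 16 in the single-end experiment, so p and q do not rank sid-1 among them.

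The 2 genes to the left of sid-1 fell with it. The files place sid-1 (WBGene00004795) on chromosome V from 5119970 to 5126916, and the annotation puts it on the plus strand. C04F5.9 (WBGene00015451) lies at 5114745 to 5119209 on the minus strand, 760 bp from sid-1, so the genes are divergent. C04F5.8 (WBGene00015450) follows at 5111497 to 5113754, also on the minus strand. These coordinates match the WBcel235 annotation. C04F5.9 fell from 32.6 to 6.26 FPKM and from 10.2 to 1.98 FPKM. C04F5.8 fell from 60.8 to 11.2 FPKM and from 47 to 11.3 FPKM. HC125 held 19.2% and 19.5% of the N2 level of C04F5.9, and 18.5% and 24% of that of C04F5.8. The log2 ratio of sid-1 minus that of C04F5.9 was -1.62 ± 0.58 in the single-end experiment (z test on the implied errors, adjusted p = 0.0166 over 6 such tests). The paired-end difference was -1.54 ± 0.80 (adjusted p = 0.0887). For sid-1 minus C04F5.8 the difference was -1.92 ± 0.55 (adjusted p = 0.00323) and -1.48 ± 0.79 (adjusted p = 0.0887).

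**Figure D1:**
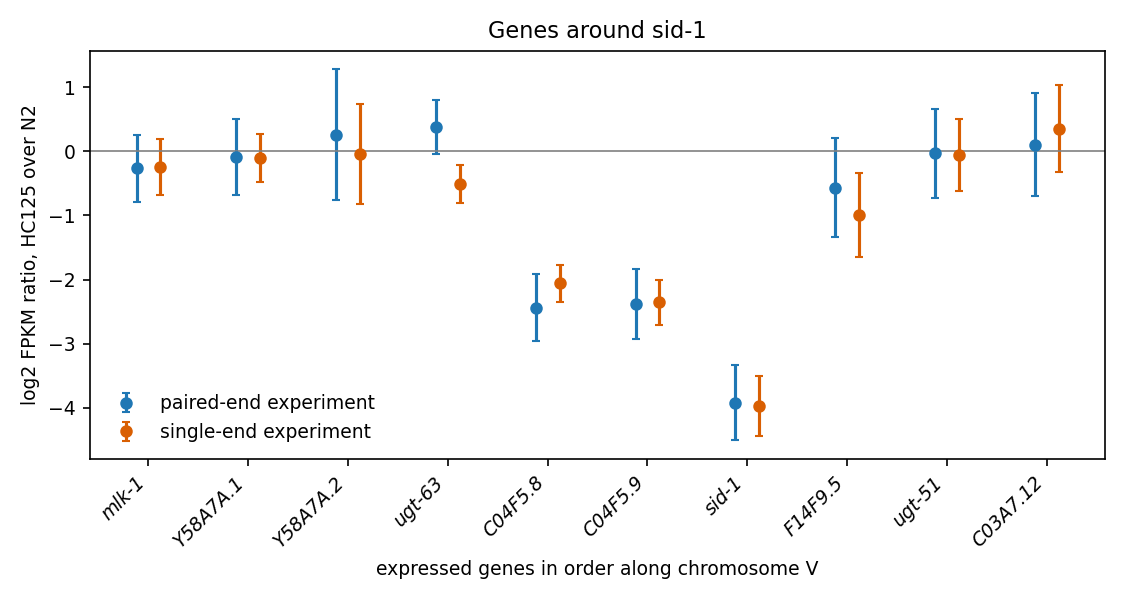
Log2 ratio of FPKM, HC125 over N2, for the 10 genes with 1 FPKM or more within 60 kb of sid-1, in their order along chromosome V. Points are the ratios of the pooled values in the paired-end (blue) and single-end (orange) experiments, and bars are ± 1 implied standard error; sid-1, C04F5.9 and C04F5.8 lie below -2 in both experiments, while the other 7 genes lie between -0.99 and 0.38.

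No other expressed gene within 60 kb was called in either table. Their median log2 ratio was -0.03 in the paired-end and -0.10 in the single-end experiment over 7 genes. ugt-63, the next gene to the left, was at 34 and 44.2 FPKM in N2 and HC125 in the paired-end experiment and at 22.9 and 16 FPKM in the single-end experiment. F14F9.5, which starts 176 bp after the end of sid-1 on the same strand, was at 4.21 and 2.85 FPKM, then at 2.14 and 1.07 FPKM. In the authors' deposited tables ugt-63 had p = 0.209 and p = 0.0140, and F14F9.5 p = 0.300 and p = 0.0356, so both flanking genes were lower at an unadjusted p under 0.05 in the single-end experiment.

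The other genes of systemic RNA interference had close levels in both strains. sid-2, an intestinal receptor for ingested double-stranded RNA, was at 9.82 FPKM in N2 and 9.28 FPKM in HC125, and at 9.72 and 9.26 FPKM in the single-end experiment. sid-5 was at 17.8 and 18.5 FPKM, then at 34.9 and 35.2 FPKM. rsd-6 was at 83.3 and 84.1 FPKM, then at 48.7 and 47.1 FPKM. sid-3, rsd-2 and rsd-3 were likewise uncalled, with log2(FPKM + 1) ratios from -0.18 to -0.01. Of the 7 listed genes, 1 fell, none rose, and the count adjusted over the list alone was also 1. The implied errors of these genes allow changes of some size: the 95% interval of the sid-2 ratio ran from 0.367 to 2.43 in the paired-end and from 0.519 to 1.75 in the single-end experiment.

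Across all genes, 5 were called in both experiments with the same direction at q of 0.05 or less, and none in opposite directions. Besides sid-1, C04F5.8 and C04F5.9, 2 genes on the left arm of chromosome V rose. F56A4.3 (WBGene00018911; 2453414 to 2456147) was listed at 0 in N2 in both experiments and at 45.8 and 65.6 FPKM in HC125. srbc-15 (WBGene00017496; 2345676 to 2348178), annotated as a pseudogene of a chemoreceptor family, was listed at 0 in N2 and at 8.18 and 5.95 FPKM in HC125. srbc-15 opens the left copy of a repeated stretch and F56A4.3 lies where the copies meet, as the closing section sets out. In the authors' deposited tables each of the 5 had p = 5e-05 in both experiments. Of 12954 genes tested in both tables, 21 and 9 were called higher, and 2 were shared against 0.0146 for independent lists (Fisher's exact test, one-sided, p = 8.95e-05). Among those 12954 genes, 5 and 7 were called lower, and 3 were shared against 0.00270 (Fisher's exact test, one-sided, p = 9.66e-10). The test treats genes as independent, but the 3 shared lower genes are neighbours and the 2 shared higher genes lie in 1 repeated stretch. Both p-values are therefore too small and overstate the evidence for sharing across separate loci.

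**Figure D2:**
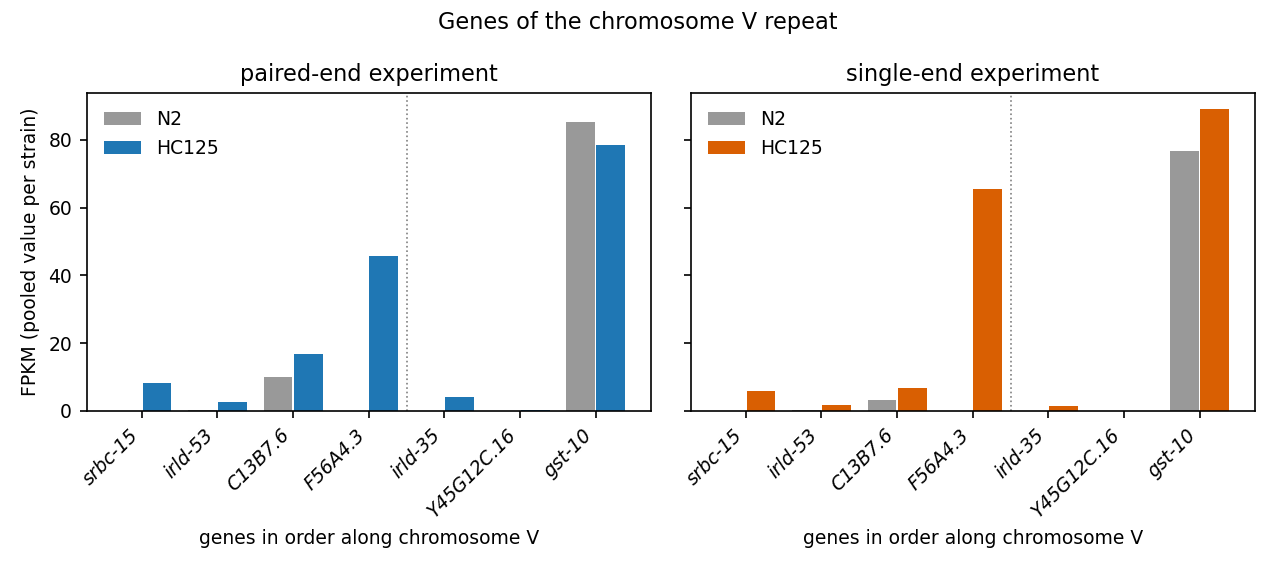
FPKM of 7 genes of the repeated stretch on chromosome V in N2 and HC125 in each experiment, with a dotted line between the left and the right copy. Bars are the authors' pooled values, and F56A4.3 and srbc-15 are listed at 0 in N2 in both experiments.

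**Figure D3:**
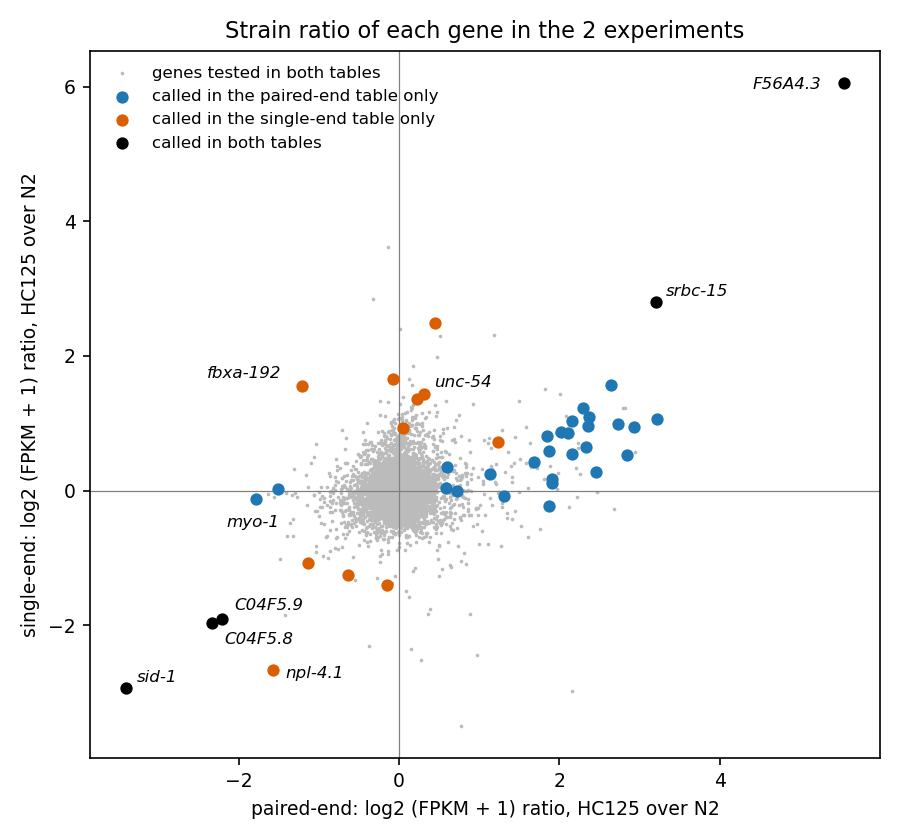
Log2(FPKM + 1) ratio of HC125 over N2 per gene, paired-end experiment on the horizontal and single-end experiment on the vertical axis. Grey points are genes tested in both tables and coloured points are those called in 1 or both; the 5 genes called in both lie far out on the diagonal, while most genes called in the paired-end table only lie at the right with smaller ratios in the single-end experiment.

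The remaining ratios were only weakly related between experiments. Over 11269 genes with 1 FPKM or more in at least 1 strain in both tables, Pearson's r of the log2(FPKM + 1) ratios was 0.232 and Spearman's rho 0.0862. Without the 5 genes called in both, r was 0.165 and rho 0.0850. These are correlations across genes, which are not independent replicates, so no p is given.

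In the paired-end experiment alone, cuticle collagen genes were the largest group called, and all of those called were higher in HC125. The authors' deposited table called 32 of 15114 tested genes, 27 higher and 5 lower in HC125. Of the 130 tested genes of the cuticle collagen list, 14 were called higher and none lower; adjusted over the list alone the numbers were 33 and 0. These genes encode the structural proteins of the worm's exoskeleton, and several are known for body shape mutants. col-73 was at 0.724 FPKM in N2 and 15 FPKM in HC125, dpy-5 at 0.739 and 12.3 FPKM, dpy-13 at 0.646 and 7.08 FPKM, and sqt-1 at 0.269 and 5.39 FPKM (chosen after their values were seen). All 4 were near the floor in N2. The list's most abundant members, col-119 and col-122, were at 2347 and 2145 FPKM, and at 1984 and 1939 FPKM. rol-1, which is not in the list, was also called higher, from 0.239 to 4.02 FPKM. In the single-end experiment none of 117 tested collagens was called, 64 were lower in HC125, and the list's median of -0.07 lay at percentile 2.36 of random lists, against 0.27 and percentile 100 in the paired-end experiment. At an unadjusted p under 0.05 in the authors' deposited tables, 41 were higher and 0 lower in the paired-end experiment, 12 were higher and 4 lower in the single-end experiment, and 11 were higher in both. Collagen genes form a large family of similar sequences, so their values can share reads.

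The myosins of the pharynx went the other way in the paired-end experiment. myo-1 was at 14.4 FPKM in N2 and 3.47 FPKM in HC125, and myo-2 at 9.12 and 2.56 FPKM; both were called lower by the authors' deposited table. In the single-end experiment they stood at 4.59 and 4.1 FPKM, and at 3.34 and 3.40 FPKM. The body wall myosin myo-3 was at 16 and 15.2 FPKM, then at 7.48 and 8.15 FPKM. The differences of myo-1 and myo-2 between experiments are given in the closing section.

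In the single-end experiment the authors' deposited table called 16 of 13150 tested genes, 9 higher and 7 lower in HC125. Outside the 5 genes called in both, the muscle myosin gene unc-54 was called higher, at 125 FPKM in N2 and 341 FPKM in HC125 (ratio 2.73, 95% interval 1.91 to 3.90). It was at 168 and 208 FPKM in the paired-end experiment, with p = 0.482 in the authors' deposited table. Among the 4 genes called lower in this experiment alone, npl-4.1 was at 25.7 and 3.20 FPKM, and at 14.4 and 4.15 FPKM in the paired-end experiment. Its neighbour npl-4.2, a gene of the same name family, was at 35.3 and 37.8 FPKM, and at 16.9 and 17.5 FPKM; whether reads were shared between them was not tested. dod-24, a gene of the innate immunity list, was at 15.6 and 5.94 FPKM, then at 15.9 and 9.88 FPKM in the paired-end experiment. F07A11.4 was at 4.56 and 1.63 FPKM, and at 11.4 and 4.67 FPKM. pgp-8, of the P-glycoprotein transporter family, was called higher, at 0.136 and 0.874 FPKM, and stood at 0.685 and 2.96 FPKM. These genes were chosen after their values were seen.

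Sperm genes had the largest list median, in the single-end experiment. There, 54 of 55 tested genes of the sperm list had a higher value in HC125, 26 of them with an unadjusted p under 0.05 in the authors' deposited table. None was called over all genes, and 7 were called higher when adjusted over the list alone. The list's median log2(FPKM + 1) ratio was 0.89, above the central 95% of matched random lists (-0.08 to 0.00). msp-152, which encodes major sperm protein, was at 32.7 FPKM in N2 and 72.5 FPKM in HC125, and msp-36 at 49.6 and 79.9 FPKM. In the paired-end experiment 40 of 62 were higher, with a median of 0.08 over the 55 tested in both tables and 1 gene, a lower one, at that p. There the ratio of HC125 over N2 was 1.16 for msp-152, and msp-36 was at 228 and 217 FPKM. The msp genes are near copies of one another, so the split of reads among them is uncertain.

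**Figure D4:**
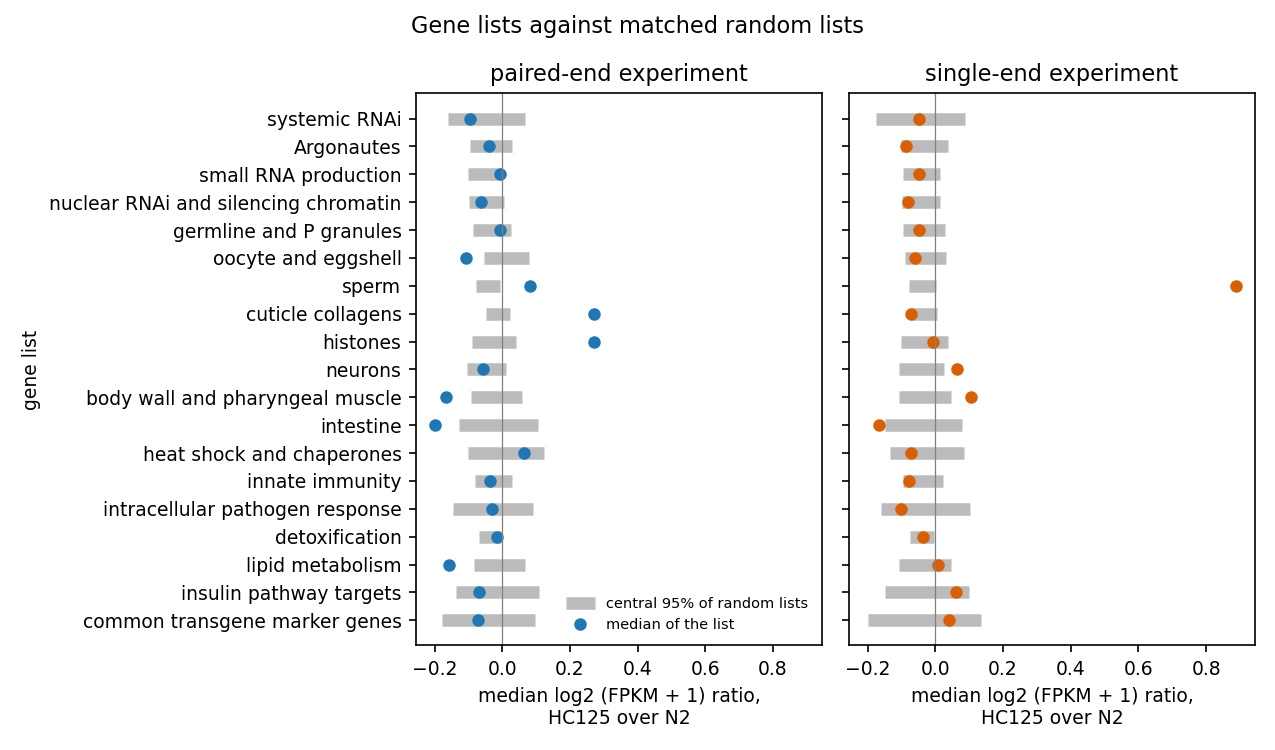
Median log2(FPKM + 1) ratio, HC125 over N2, of 19 gene lists (rows) in the paired-end (left) and single-end (right) experiments. Points are list medians and grey bars the central 95% of 10000 random lists matched on size and level; the sperm list stands at 0.08 and 0.89, and the cuticle collagen list at 0.27 and -0.07.

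Among other tissue, stage and metabolic markers, the intestine, muscle, oocyte, histone, neuron and lipid lists had medians outside the central 95% of random lists in at least 1 experiment. The median of the 7 intestine genes was -0.20 and -0.17, below the central 95% of random lists in both experiments; asp-1, a gut protease, was at 1101 and 990 FPKM, then at 5009 and 4268 FPKM. The body wall and pharyngeal muscle list was below its random range in the paired-end experiment (-0.17) and above it in the single-end experiment (0.10). Oocyte and eggshell genes had medians of -0.11 (below the range) and -0.06, with cpg-2 at 1382 and 1211 FPKM, then at 2241 and 2013 FPKM. Germline and P granule genes had medians of -0.01 and -0.05, with the RNA-binding regulator gld-1 at 648 and 612 FPKM, then at 435 and 398 FPKM. Histones had medians of 0.27 (above the range, as for collagens in that experiment) and -0.01, and neuron genes of -0.06 and 0.06 (above the range). Lipid metabolism genes stood at -0.16 (below the range) and 0.01. None of these lists but muscle held a gene called in either table. Of the yolk genes, vit-1 was tested in both tables, at 1859 and 1572 FPKM, then at 1286 and 1298 FPKM, while others lacked a usable estimate in at least 1 table.

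Genes of the RNA interference machinery had close levels in both strains. No Argonaute gene, no gene of small RNA production and no gene of the list of nuclear RNA interference and silencing chromatin had an unadjusted p under 0.05 in either of the authors' deposited tables. Over all tested genes only 1.28% and 2.39% had such a p, so its absence from these lists says little. The medians of the 20 Argonaute genes were -0.04 and -0.09, those of the 29 genes of small RNA production -0.01 and -0.05, and those of the 24 nuclear genes -0.06 and -0.08, all within the central 95% of random lists. hrde-1, the germline nuclear Argonaute, was at 281 FPKM in N2 and 239 FPKM in HC125, and at 185 and 174 FPKM. The 95% interval of its ratio ran from 0.443 to 1.62 in the paired-end and from 0.663 to 1.32 in the single-end experiment. wago-1 was at 272 and 265 FPKM, then at 289 and 250 FPKM. rde-4, the double-stranded RNA binding partner of Dicer, was at 131 and 134 FPKM, then at 106 and 103 FPKM. mrg-1 was at 149 and 145 FPKM, then at 161 and 157 FPKM.

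Stress, immune and metabolic lists held 2 calls, both in the single-end experiment: dod-24, given above, and ugt-64 of the detoxification list, called higher at 13.7 and 26.9 FPKM (54.9 and 56.8 FPKM in the paired-end experiment). The medians were 0.06 and -0.07 for heat shock genes and chaperones, -0.04 and -0.08 for innate immunity, -0.03 and -0.10 for the intracellular pathogen response, -0.01 and -0.04 for detoxification, and -0.07 and 0.06 for insulin pathway targets. All lay within the central 95% of random lists. Genes often used to mark transgenes had medians of -0.07 and 0.04. In the paired-end experiment 1 of them, myo-2, was called lower, and adjusted over the list alone 1 was higher and 1 lower; in the single-end experiment none was called. unc-119 among them was at 17.6 and 17.2 FPKM, then at 16.9 and 19.3 FPKM.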

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

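Apart from the Stouffer combination, all tests in this section were chosen after the results were seen. Among them is the list of moulting genes, which was written after the collagen calls and before its own values were computed. The 35 genes called in at least 1 table with an implied error in both were compared between experiments (z test on the implied errors, Benjamini-Hochberg adjusted). At this adjustment the ratio differed for 7 of them, but a call in 1 table was part of their selection, which favours a difference. Over all 12921 genes with an implied error in both tables, called or not, only fbxa-192 passed (adjusted p = 0.00572). The other 6 had an adjusted p of 1.00, so their differences are not established on the implied errors. Those errors are often wider than the deposited p-values imply, so this z test can miss differences. fbxa-192, of an F-box family with many similar members, had a log2 ratio higher by 2.96 in the single-end experiment (adjusted p = 1.55e-05 over the 35), at 30.0 FPKM in N2 and 12.4 FPKM in HC125 in the paired-end experiment and at 6.55 and 21 FPKM in the other. The difference of single-end minus paired-end was 1.89 for myo-1 (adjusted p = 0.0186), 1.86 for myo-2 (adjusted p = 0.0226) and 2.31 for asm-3 (adjusted p = 0.0201). It was -3.13 for F41F3.3 (adjusted p = 0.0232), -1.48 for F25E5.1 (adjusted p = 0.0258) and -2.48 for W06A11.4 (adjusted p = 0.0258). Library kit, strandedness and read layout all differ between the experiments and cannot be separated for these genes, nor from any difference of batch, which the labels do not give. For sid-1 the difference was -0.06 (adjusted p = 0.968).

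A set of cuticle collagens was higher in HC125 in the paired-end experiment, and a chance fluctuation of those libraries alone is argued against by the other experiment. There all 14 were higher, although the median of the whole collagen list was -0.07. Of the 12 tested, 7 had an unadjusted p under 0.05 in the authors' deposited table, though genes that move together are not 14 independent signs. Their levels there were low, at most 3.62 FPKM in N2 and from 0.0625 to 7.58 FPKM in HC125, so some signs rest on values near the floor. Cultures staged differently around a moult may account for the paired-end values, since the median of 17 other moulting genes lay at percentile 99.98 of matched random lists (0.18). In the single-end experiment that median was -0.23, at percentile 0.02, which argues against the same shift there; the sperm list's median was 0.89 in the same libraries, and whether stage accounts for both was not tested. A strain difference in collagen expression stays open and was not tested apart from staging.

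The genes srbc-15 and F56A4.3, both listed at 0 in N2, sit in a stretch of chromosome V from 2345676 to 2564708 that holds a left and a right copy. Of the 27 genes of the left copy, 26 have a counterpart about 108279 bp to the right, 19 of them of the same length. From srbc-15 to F56A4.3, 23 of 27 genes were listed at 0 in N2 in both experiments, so that value is common in this stretch. Reads of gst-10 and F56A4.3, which hold matching places in the 2 copies, shared out differently would leave their summed FPKM level. The sum was 1.46 and 2.02 times higher in HC125, with z of 0.861 in the paired-end and 2.55 in the single-end experiment (2.41 combined). The error of the sum was assumed to be that of gst-10 times the square root of 2. Such sharing would also lower gst-10 by what F56A4.3 gained, 45.8 and 65.6 FPKM. In the paired-end experiment gst-10 was at 85.2 FPKM in N2 and 78.4 FPKM in HC125 (95% interval of the ratio 0.502 to 1.69). It was at 76.8 and 89.2 FPKM in the single-end experiment (0.794 to 1.70). The single-end values argue against shared reads there, while the paired-end sum leaves them open. A single copy in the N2 stock against 2 copies in HC125 could give such sums. The pair C13B7.6 and Y45G12C.16 was at 1.68 and 2.22 times. Over the 2 pairs with an N2 sum of 1 FPKM or more in both experiments, the mean was 1.84 times. The 18 genes flanking the stretch within 100 kb had a median ratio of 0.97 in the paired-end and 1.07 in the single-end experiment. Of the pairs with low sums in N2, under 1 FPKM but above 0 in both experiments, Y19D10A.11 and F56A4.12 stood at 4.32 and 5.73 times. Y19D10A.8 and F56A4.10 stood at 3.63 and 2.12 times. The mean over the 3 pairs with a sum of 1 FPKM or more in at least 1 strain in both experiments, 9.64, is carried by irld-53 and irld-35 (20.5 and 30.0 times). The sums of that pair were near the floor in N2, at 0.323 and 0.101 FPKM, against 6.63 and 3.03 FPKM in HC125. The 95% interval of the irld-53 ratio, 2.08 to 36.6 and 7.12 to 44.8, lay above 2 in both. This pair goes beyond a plain 2 to 1 difference, but with N2 sums near the floor it decides nothing for the stretch. Copy number, a rearrangement of another kind and a change in the activity of these genes all stay open, since genomic reads were not used here.

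The muscle myosin gene unc-54 and its neighbour aex-5, which lies 71 bp beyond its 3' end on the same strand, had higher values in HC125 in both experiments, but of these only unc-54 in the single-end experiment was called. aex-5 was at 12 and 34.4 FPKM, then at 6.62 and 12.2 FPKM, with p = 0.00770 and p = 0.00555 and q = 1.00 in both of the authors' deposited tables, though the Stouffer combination of both called it higher (adjusted p = 0.0459); unc-54 had p = 0.482 in the authors' deposited paired-end table. More muscle RNA in the HC125 worms is argued against by the other 15 muscle genes, whose median log2(FPKM + 1) ratio in the single-end experiment was 0.10 (SD over genes 0.15) against 1.44 for unc-54. Transgene RNA that carries the 3' end of unc-54, a common part of worm expression vectors, cannot be told apart from a change at the native locus. The lowest of the 4 ratios, 0.31 for unc-54 in the paired-end experiment, lies within its implied SE of 0.63 from 0 and decides nothing, and the transgene's sequence was not used here.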

How the results depend on the processing

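The unadjusted threshold and the sid-1 ratio without a pseudocount were added after seeing the data; the other alternatives were set before. At q of 0.01 or less the counts were 0 in the paired-end experiment, 0 in the single-end experiment and 0 in both. This holds by construction, since the lowest q of the deposited tables is 0.0270 and 0.0411. The counts at an unadjusted p under 0.05 are 193 and 314, or 1.28% and 2.39% of the tested genes. That is a smaller share than p-values spread evenly from 0 to 1 would give, so an unadjusted p here is not calibrated across genes. The FPKM filter left 29 and 15 genes and the minimum log2 ratio of 1 left 29 and 14, with 5 in both each time. The Stouffer combination called 35 genes, 24 higher and 11 lower, the 5 among them. limma on the 2 ratios called 0, with 694 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0563 (F56A4.3); it also called none of the simulated changes, so its count says nothing about stability. An unadjusted p under 0.05 in both tables gave 38 genes with the same direction and 8 with opposite directions, against 1.61 and 1.56 for independent lists. Since the opposite count also exceeds its expectation, independence is a poor yardstick here. The 38 also include 11 genes of the collagen list, and sid-1 with its neighbours C04F5.8 and C04F5.9, so they are not 38 separate observations. The log2 ratio of sid-1 ranged from -3.92 to -2.38 in the paired-end and from -3.98 to -1.62 in the single-end experiment, the smaller size in each at a pseudocount of 5. Pearson's r was 0.311 at a minimum of 10 FPKM. The lists outside the central 95% of random lists on the same side in both experiments were 2 (sperm and intestine), and again 2 in number at each other pseudocount and with the filter; centring cannot change this count or, in practice, that of calls, which rest on the deposited q. Taken alone, the paired-end experiment gave 7 and the single-end experiment 5. Of 38 list medians, centring moved 18 and a pseudocount of 5 moved 3. No paired analysis was possible because each table gives 1 value per strain and no value per library; for the same reason leaving out replicates and other tools on library values were not run. Depth is unknown, and the implied errors set what could be seen: a median of 0.59 on the log2 scale in the paired-end experiment.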

Other observations

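The genes given here were chosen after their values were seen. Several genes outside the fixed lists had the same direction in both experiments without being called in both. By the Stouffer combination, C45E5.4 (adjusted p = 0.00308), F23F12.12 (adjusted p = 0.00837) and asfl-1 (adjusted p = 0.0147) were lower in HC125. Their log2(FPKM + 1) ratios were -1.48 and -1.02, -1.40 and -0.67, and -0.78 and -0.69. egas-3 was higher (adjusted p = 0.00837), with ratios of 0.87 and 0.74. Among collagens not called in either table, col-97, col-104 and col-109 were higher, with ratios of 1.95 and 0.85, 2.09 and 1.11, and 1.63 and 0.71. The hedgehog-related gene wrt-10 and the moulting gene mlt-8 had ratios of 0.99 and 1.04 in the paired-end experiment, and of -0.36 and -0.61 in the single-end experiment.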
